A study of Curvularia clavata with 15 samples.

How the data were processed

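The data were RNA-seq libraries of mycelia of Curvularia clavata strain J1, grown in 100 mL of Vogel's minimal medium at 30 °C and 200 rpm for 4 days, per the labels. RNA was extracted with TRIzol and cleaned on columns, and libraries were made by Illumina protocols, per the labels' protocols. The labels gave genotype, carbon source and sample number for each of the 15 libraries, 3 in each of 5 groups. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

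Each deposited file held 1 value per gene ID for 1 library. The values are FPKM, fragments mapped to a transcript scaled by its length and by the mapped total of the library, per the file headers of 6 libraries. The headers of the other 9 name no unit, and their values have the same form and range. The 6 are the WT libraries and the 9 the mutant libraries, so each contrast of a mutant with WT also sets one kind of file against the other, and whether all were processed together is not given in the sources used here. The submitters' processing notes name fastp 0.19.5, HISAT2 2.1.0, RSEM 1.3.3 and DESeq2 without giving their roles. The genome build and annotation are not given in the sources used here. FPKM is relative to the library's own total, so a few very abundant transcripts lower the values of all others. No read counts were used here, and count models were not run.

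The number of reads per library is unknown from FPKM. Relative depth was estimated from the smallest steps of values between 0.08 and 0.6 FPKM, since 1 fragment is worth more in a shallower library. Of 105 pairs of libraries, 91.4% fitted the estimated depths within 0.05 on the log2 scale. Estimates ran from 0.685 in WT on glucose replicate 2, with a bootstrap range of 0.672 to 1.28 over 50 draws, to 1.13 in WT on lignosulfonate replicate 3. No replicate pair held identical files, and at most 1.50% of the FPKM values of tested genes were identical within a pair.

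Genes with at least 1 FPKM in at least 3 libraries were tested, 9265 of 10170, and 354 IDs were listed at 0 in every library. The values were transformed to log2(FPKM + 1), a scale that understates changes of genes with low values. Linear models with a mean per group were fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, using the trend and robust options. Contrasts were WT on lignosulfonate against glucose, each mutant against WT on lignosulfonate, and each pair of mutants. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. These choices, the grouping and the alternatives were made before the data were examined, except where an alternative is said to be added.

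Alternatives were a pseudocount of 0.1, no filter, FPKM rescaled to equal sums (TPM), division by median-of-ratios size factors, only the 6 libraries compared, the replicate number as a block, no minimum fold change, and leaving out each replicate. Removing the 100 most abundant genes, ranked by mean FPKM over all 15 libraries, was added after the low medians of Δrpn-4 were seen. Lists of calls were compared with Fisher's exact test and with 100 simulations of unchanged groups that share the same control libraries. Adjacency of called IDs was tested by 100000 random reassignments of IDs to positions. Further steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

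The fit was tested on simulated data with 100 genes changed at each size. The changed genes had a mean of at least 3 on the log2(FPKM + 1) scale in the group compared against. Noise was drawn independently for each gene and library from the spread fitted to these data, the same in all groups. No shift of library scale or composition was simulated. Recovery and false calls below therefore do not measure errors from scaling or from an aberrant library. Recovery of genes below that level was not tested, and the gene numbers in brackets are all genes in each fit. At a log2 change of 1.5 it recovered 96% for lignosulfonate against glucose (9222 genes), 99% for ΔCclaeA (9233 genes), 97% for Δrpn-4 (9235 genes) and 98% for Δtah-1 (9211 genes), each against WT, with 3, 1, 2 and 3 false calls.

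The rule for named genes, fixed before the data were examined, was to print the 2 IDs with the largest rise and the 2 with the largest fall among called genes of each main contrast where IDs could not be matched to an annotation. No ID was matched to a gene name here. Gene list tests, motif lists, the laccase list and the levels of the 3 deleted genes were therefore not run. Any other ID printed was chosen after its values were seen.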

Results

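Curvularia clavata is a filamentous fungus. RNA from mycelia of strain J1 was sequenced to ask how the wild type (WT) responds to lignosulfonate, a water-soluble sulfonated lignin, and how loss of CclaeA, rpn-4 or tah-1 alters the transcriptome on that substrate. The series held 15 libraries in 5 groups of 3. WT was grown on 2% glucose or on 2% lignosulfonate with 0.25% glucose, and the ΔCclaeA, Δrpn-4 and Δtah-1 mutants were grown on the lignosulfonate medium. All cultures were shaken for 4 days. LaeA proteins are known in filamentous fungi as regulators of secondary metabolism, and Rpn4 of budding yeast is a transcription factor of proteasome genes.

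Each library listed FPKM for 10170 gene IDs, of which 9265 passed the expression filter. The IDs were not paired with gene names in the sources used here, so genes are named by ID only. The FPKM sum per library ran from 662880 in Δtah-1 replicate 1 to 1186753 in WT on glucose replicate 2. The median FPKM was 32.9 ± 1.78 (SD, n = 3) in WT on lignosulfonate, 27.0 ± 0.489 in WT on glucose, 30.4 ± 0.351 in ΔCclaeA, 17.5 ± 0.144 in Δrpn-4 and 25.0 ± 4.80 in Δtah-1. The Δtah-1 spread came mainly from replicate 2, with a median of 30.5 against 21.4 and 23.1 in replicates 1 and 3. In Δrpn-4 the 10 most abundant IDs held 25.9% ± 0.517 of the FPKM sum, against 11.9% ± 0.152 in WT on lignosulfonate. The first principal component carried 56.5% of the variance and separated glucose from lignosulfonate libraries, and components 2 and 3 carried 16.9% and 15.4% and separated the genotypes.

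**Figure D1:**
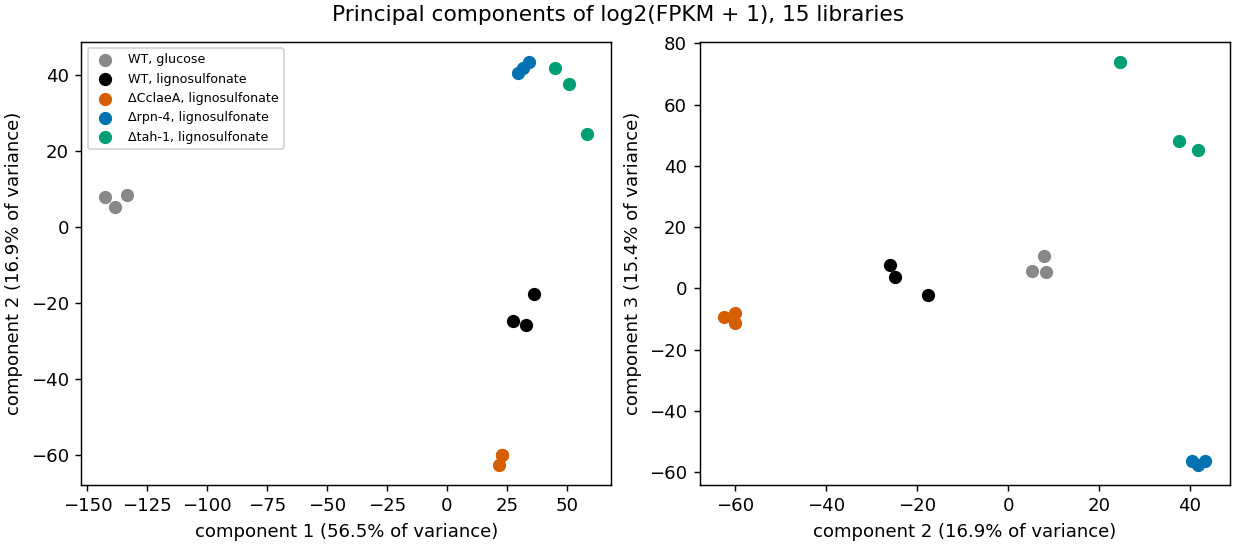
Principal components 1 and 2 (left) and 2 and 3 (right) of log2(FPKM + 1), 1 point per library and 1 colour per group, with the percentage of variance on each axis. The 3 libraries of each group lie together, component 1 (56.5% of variance) separates WT on glucose from the rest, and Δtah-1 replicates are the most spread of the mutants.

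The first comparison asked which genes respond to lignosulfonate in WT. Between the lignosulfonate and the glucose medium 3760 IDs differed, 2405 higher and 1355 lower on lignosulfonate. The media differ in lignosulfonate (2% against 0) and in glucose (0.25% against 2%), and the effects of these cannot be told apart in this comparison. yc1106_09585 rose from 2.74 ± 1.80 FPKM on glucose to 25517 ± 1596 on lignosulfonate (SD, n = 3 each), a log2 fold change of 12.86 (SE 0.34, limma adjusted p = 8.25e-14). yc1106_06939 rose by a log2 fold change of 10.92 (SE 1.2, limma adjusted p = 4.43e-06), with wide replicate spread, from 18.1 ± 31.3 to 8747 ± 5582 FPKM. Its glucose libraries were listed at 54.3, 0 and 0 FPKM, and the log2 fold change was 12.85 without WT on glucose replicate 1, 9.96 without replicate 2 or 3, and 11.51 without WT on lignosulfonate replicate 3. The SE pools the spread of all 5 groups. With only the 6 compared libraries the limma adjusted p for yc1106_06939 was 0.00381. yc1106_06671 went the other way, from 5510 ± 1459 FPKM on glucose to 0.020 ± 0.035 on lignosulfonate (log2 fold change -12.37, SE 0.17, limma adjusted p = 2.28e-16). yc1106_04105 fell from 2771 ± 569 to 0.197 ± 0.095 FPKM (log2 fold change -11.16, SE 0.19, limma adjusted p = 6.75e-16).

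The fold changes of IDs near 0 depend on the pseudocount. At least 16-fold increases were called for 331 IDs and at least 16-fold decreases for 125. A set of 148 IDs had at least 10 FPKM in all 3 lignosulfonate libraries and under 1 FPKM in all 3 glucose libraries, and 38 IDs had the opposite pattern. After median-of-ratios scaling, 2104 IDs were higher and 1673 lower, and 2103 and 1353 of the calls were shared with the unscaled values.

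Some of these IDs sat next to one another in the ID numbering. The 3 runs described here were chosen after the values were seen, and whether ID order follows genome order is not given in the sources used here. All 7 IDs from yc1106_06668 to yc1106_06674 were lower on lignosulfonate, with a median of the group means of 179 FPKM on glucose and 0.103 on lignosulfonate, and none of the 7 was called different from WT in a mutant. All 5 IDs from yc1106_01886 to yc1106_01890 were higher on lignosulfonate, with a median of 0.20 FPKM on glucose and 354 on lignosulfonate. In Δtah-1 all 5 were lower than in WT, with a median of 5.72 FPKM, and in ΔCclaeA 4 of the 5 were higher, with a median of 685 FPKM. In Δrpn-4, 4 of the 5 were lower as deposited and 1 after median-of-ratios scaling, with a median of 182 FPKM. The 9 IDs from yc1106_02302 to yc1106_02310 rose on lignosulfonate from a median of 2.32 to 19.2 FPKM, and 8 of them were higher again in Δtah-1, with a median of 256 FPKM.

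**Figure D2:**
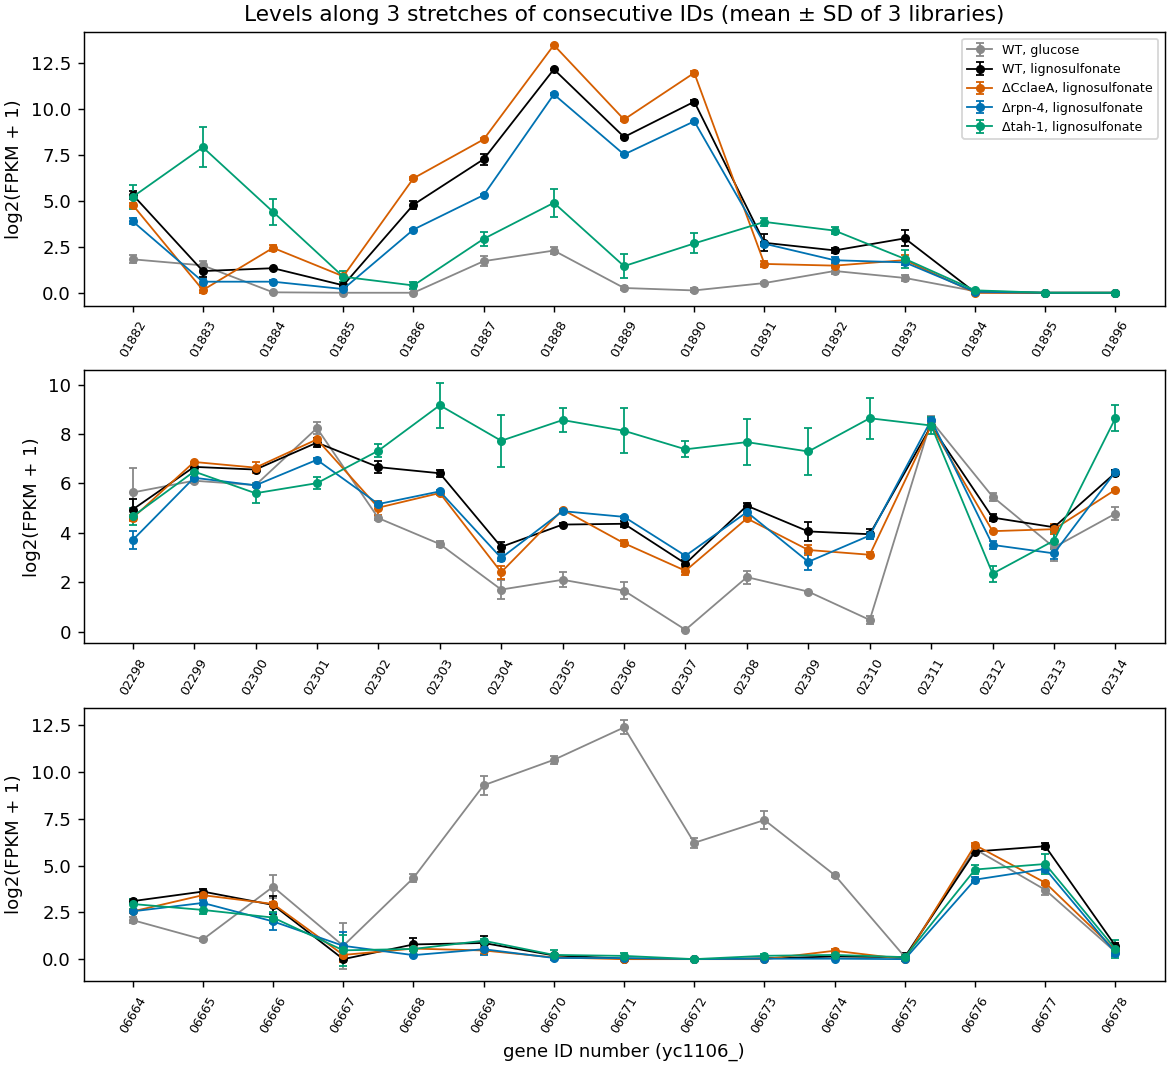
Log2(FPKM + 1) along 3 stretches of consecutive IDs chosen after the values were seen; each point is a group mean and each bar the SD of 3 libraries. The IDs yc1106_01886 to yc1106_01890 are high on lignosulfonate except in Δtah-1, yc1106_02302 to yc1106_02310 are highest in Δtah-1 (median 256 FPKM), and yc1106_06668 to yc1106_06674 are high on glucose (median 179 FPKM).

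The next 3 comparisons asked what each deletion changes on lignosulfonate. The deleted genes themselves were not identified among the IDs, so the genotype labels were not checked against the values. An ID that falls to near 0 in 1 mutant could be the deleted gene itself. The WT files name FPKM in their headers and the mutant files do not, so a processing difference common to the mutant files would enter all 3 of these comparisons alike, but not the contrasts between mutants. In ΔCclaeA, 1164 IDs differed from WT, 312 higher and 852 lower. yc1106_05659 rose from 4.40 ± 0.869 FPKM in WT to 859 ± 30.2 (SD, n = 3 each; log2 fold change 7.33, SE 0.25, limma adjusted p = 1.77e-11). yc1106_06554 rose from 4.86 ± 0.705 to 827 ± 62.5 FPKM (log2 fold change 7.15, SE 0.18, limma adjusted p = 1.02e-12). Their means in the other mutants lay between 2.54 and 8.48 FPKM. yc1106_04001 fell from 411 ± 18.2 to 0.213 ± 0.167 FPKM (log2 fold change -8.42, SE 0.19, limma adjusted p = 3.94e-13). It was also lower in Δtah-1, at 59.3 ± 8.12 FPKM (log2 fold change -2.78, and -2.38 with median-of-ratios scaling). yc1106_04083 fell from 3385 ± 539 to 29.2 ± 9.28 FPKM (log2 fold change -6.85, SE 0.24, limma adjusted p = 3.73e-11). The median log2 fold change of all tested IDs was -0.11. With median-of-ratios scaling the split was 403 higher and 656 lower, so that the share of higher calls was 38.1% in place of 26.8%.

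In Δrpn-4, a few very abundant IDs rose and the bulk of the other IDs had lower FPKM. yc1106_07373 rose from 989 ± 253 FPKM in WT to 21224 ± 999 (SD, n = 3 each; log2 fold change 4.45, SE 0.21, limma adjusted p = 2.49e-09). yc1106_04000 rose from 26.6 ± 2.56 to 1635 ± 140 FPKM (log2 fold change 5.89, SE 0.62, limma adjusted p = 2.8e-06). yc1106_04924 fell from 251 ± 48.8 to 22.7 ± 3.96 FPKM (log2 fold change -3.41, SE 0.26, limma adjusted p = 1.78e-07). It was also lower than in WT in ΔCclaeA, at 9.79 ± 0.866 FPKM (log2 fold change -4.53), and higher in Δtah-1, at 541 ± 160 FPKM. yc1106_02960 fell from 444 ± 41.6 to 43.7 ± 3.33 FPKM (log2 fold change -3.31, SE 0.21, limma adjusted p = 3.94e-08). In ΔCclaeA it was called lower as deposited (log2 fold change -1.06) but not after scaling (-0.95). After median-of-ratios scaling the log2 fold changes were 6.74 for yc1106_04000, 5.32 for yc1106_07373, -2.56 for yc1106_04924 and -2.46 for yc1106_02960. Both falls were smaller than the largest falls in the other mutants, and no ID was called at least 16-fold lower in Δrpn-4. As deposited, 3503 IDs differed, 269 higher and 3234 lower, around a median log2 fold change of -0.79. Median-of-ratios scaling gave 1203 calls, 906 higher and 297 lower, so the direction of the balance depended on the scaling. The calls made under both scalings were 269 higher and 297 lower, and no ID was called in opposite directions.

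**Figure D3:**
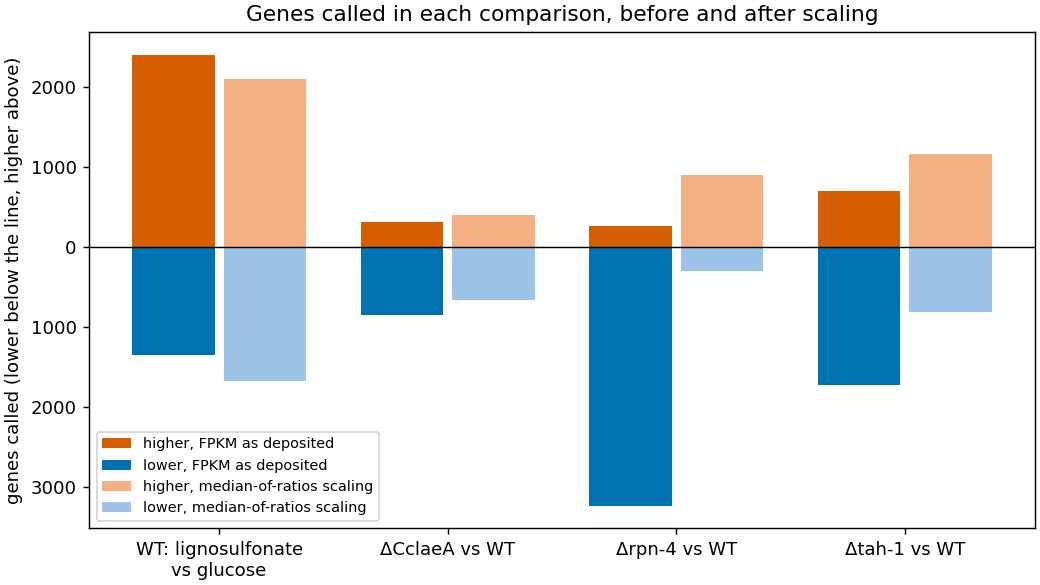
Number of IDs called higher (above the line) and lower (below the line) in 4 comparisons, for FPKM as deposited (dark bars) and after median-of-ratios scaling (light bars). The Δrpn-4 bars turn from 269 higher and 3234 lower to 906 higher and 297 lower.

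In Δtah-1, 2434 IDs differed from WT, 706 higher and 1728 lower. yc1106_01883 rose from 1.3 ± 0.494 FPKM in WT to 293 ± 233 (SD, n = 3 each; log2 fold change 6.73, SE 0.38, limma adjusted p = 4.18e-09), with a range of 127 to 560 FPKM in the mutant and a log2 fold change of 6.12 without replicate 2. With only the 6 compared libraries its limma adjusted p was 2.32e-05. yc1106_01726 rose from 5.37 ± 0.905 to 182 ± 20.1 FPKM (log2 fold change 4.85, SE 0.18, limma adjusted p = 8.6e-11). yc1106_06359 fell from 314 ± 5.37 to 0.483 ± 0.458 FPKM (log2 fold change -7.78, SE 0.19, limma adjusted p = 1.2e-12). yc1106_01890 fell from 1344 ± 104 to 5.72 ± 2.39 FPKM (log2 fold change -7.71, SE 0.20, limma adjusted p = 1.58e-12). In the other mutants yc1106_06359 was higher than in WT in Δrpn-4, at 969 ± 48.8 FPKM, and lower in ΔCclaeA, at 74.9 ± 5.31 FPKM. yc1106_01890 was higher in ΔCclaeA, at 3982 ± 252 FPKM, and in Δrpn-4 it had 640 ± 14.5 FPKM, called lower as deposited (log2 fold change -1.07) but not after scaling (-0.20). The median log2 fold change of all tested IDs was -0.37. With median-of-ratios scaling the split was 1161 higher and 814 lower, and 706 and 814 IDs were called under both scalings.

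The mutants were then compared with one another. ΔCclaeA and Δrpn-4 differed in 3506 IDs, 2915 of them higher in ΔCclaeA, and after scaling in 2053, of which 706 were higher in ΔCclaeA. ΔCclaeA and Δtah-1 differed in 3227 IDs, 1962 higher in ΔCclaeA, and after scaling in 3017, of which 1355 were higher. Δrpn-4 and Δtah-1 differed in 2903 IDs, 709 higher in Δrpn-4, and after scaling in 2433, of which 1285 were higher. Rescaling to equal sums (TPM) moved the last split the other way, to 451 higher and 3780 lower in Δrpn-4.

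The most abundant IDs of Δrpn-4 moved in opposite directions in the mutants. Of the 10 IDs with the highest mean FPKM in Δrpn-4, 9 were called higher there than in WT, a direction that choosing them by their level in Δrpn-4 favours, and 8 of them were also lower in both ΔCclaeA and Δtah-1, with either scaling. One of them, yc1106_07527, chosen after its values were seen, had 17807 ± 1547 FPKM in WT on lignosulfonate, 64455 ± 1925 in Δrpn-4, 444 ± 150 in ΔCclaeA and 1126 ± 194 in Δtah-1 (SD, n = 3 each). The named yc1106_04083 had 15276 ± 318 FPKM in Δrpn-4 and 121 ± 40.1 in Δtah-1, with 29.2 ± 9.28 in ΔCclaeA. In all, 51 IDs were higher in Δrpn-4 and lower in ΔCclaeA and Δtah-1, where 4.61 would be shared by independent lists. With median-of-ratios scaling the set had 68 IDs against 5.65, and 43 IDs were in both sets. Because the 51 IDs were selected by these directions, their shares describe the set and test nothing. They held 31.8% ± 0.519 of the FPKM sum in Δrpn-4, 7.38% ± 0.885 in WT on lignosulfonate, 2.87% ± 0.342 in WT on glucose, 0.663% ± 0.060 in ΔCclaeA and 0.925% ± 0.106 in Δtah-1 (SD, n = 3 each). On lignosulfonate 27 of the 51 were higher than on glucose in WT and 2 were lower.

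**Figure D4:**
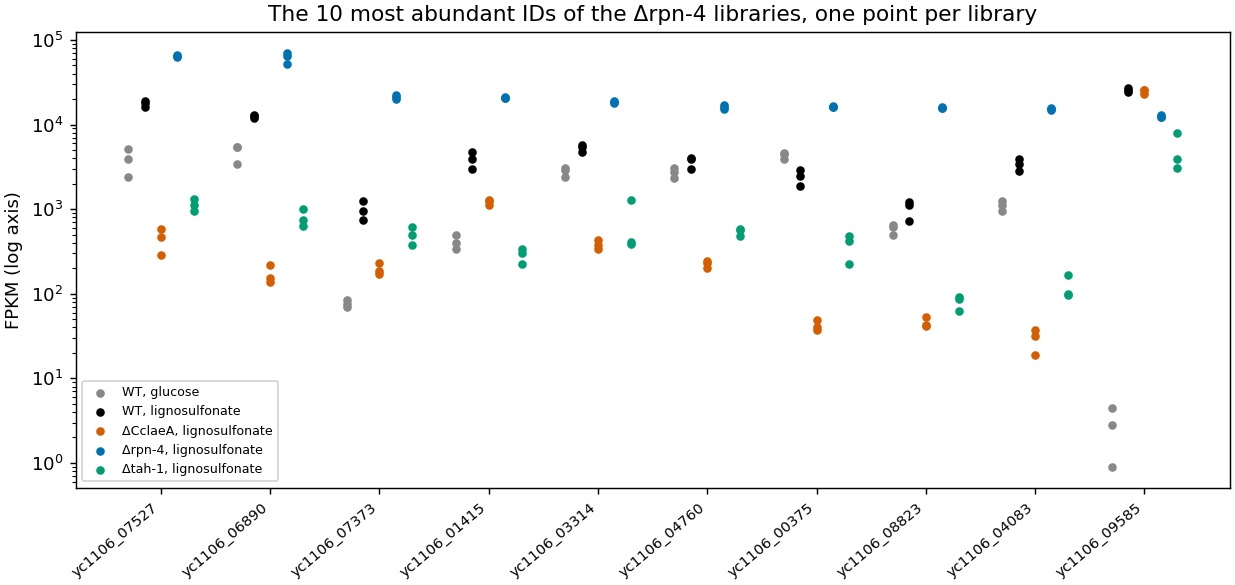
FPKM on a log axis for the 10 IDs with the highest mean FPKM in Δrpn-4, 1 point per library and 1 colour per group. For 9 of the 10 the Δrpn-4 points lie above all other groups, and for 8 of these ΔCclaeA and Δtah-1 were both called lower than WT on lignosulfonate.

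Lists of calls were compared between mutants with Fisher's exact test (two-sided, 24 overlaps per scaling, Benjamini-Hochberg adjusted). Overlaps in opposite directions between mutants were added after the calls were seen. Genes are not independent replicates, and all mutants were set against the same 3 WT libraries. ΔCclaeA and Δrpn-4 shared 336 IDs that were lower, against 297 for independent lists (Fisher's exact test, adjusted p = 0.00551), and 79 against 21.1 with median of ratios. ΔCclaeA and Δtah-1 shared 259 IDs that were lower, against 159 for independent lists (Fisher's exact test, adjusted p = 8.31e-18). Of the IDs lower in ΔCclaeA, 152 were higher in Δtah-1, against 64.9 (Fisher's exact test, adjusted p = 1.14e-24), and 88 were higher in Δrpn-4, against 24.7 (Fisher's exact test, adjusted p = 4.05e-27). Δrpn-4 and Δtah-1 shared 772 lower IDs, against 603. With median of ratios the last 4 of these overlaps held 159, 170, 148 and 58 IDs, against 57.7, 82.3, 64.2 and 26.1. IDs higher in both mutants numbered 12 for ΔCclaeA and Δrpn-4, 38 for ΔCclaeA and Δtah-1 and 46 for Δrpn-4 and Δtah-1, against 9.06, 23.8 and 20.5 for independent lists (Fisher's exact test, adjusted p = 0.301, 0.0056 and 2.94e-07). With median of ratios they numbered 61, 68 and 238, against 39.5, 50.6 and 114 (Fisher's exact test, adjusted p = 0.000743, 0.0131 and 8.1e-32). For ΔCclaeA and Δtah-1 every combination of directions lay above independent lists. This included 107 IDs higher in ΔCclaeA and lower in Δtah-1, against 58.2. The excess for this pair therefore does not show sharing in a particular direction. Groups simulated without effects against the same controls shared at most 1 call in the same direction, but such groups yield almost no calls, so that number does not measure what the shared controls add. Across genes, fold changes correlated at 0.00 for ΔCclaeA with Δrpn-4, -0.02 for ΔCclaeA with Δtah-1 and 0.12 for Δrpn-4 with Δtah-1, where the shared controls alone gave 0.50 in each. The 0.50 holds for groups without effects and follows from sharing a control. Real effects change the spread of fold changes, so the observed correlations cannot be set against 0.50, and covariances were compared instead. The covariance lay below the simulated one by -0.025 and -0.037 for the first pairs and above it by 0.061 for the last. With 3 control libraries the controls could not be split into 2 parts of at least 2 libraries, so part of a shared count can come from the shared controls.

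The last comparison asked how the mutants stood on the IDs that differ between the lignosulfonate and glucose media in WT, where lower glucose and lignosulfonate cannot be told apart. Of the 2405 IDs higher on lignosulfonate, 497 (20.7%) were lower in ΔCclaeA, against 221 for independent lists (Fisher's exact test, adjusted p = 2.39e-97), and after scaling 393 against 149. In Δrpn-4, 974 were lower, against 839 (Fisher's exact test, adjusted p = 7.42e-11), and after scaling 147 against 67.5. Of the same 2405 IDs, 117 were higher in ΔCclaeA, against 81.0, and 98 in Δrpn-4, against 69.8. After scaling, 120 and 263 were higher, against 91.6 and 206. In Δtah-1, 412 were lower, against 449 (Fisher's exact test, adjusted p = 0.0275), whereas 332 were higher, against 183 (Fisher's exact test, adjusted p = 4.74e-35). After scaling, 207 were lower in Δtah-1, against 185 (Fisher's exact test, adjusted p = 0.065), and 476 were higher, against 264. Of the 1355 IDs lower on lignosulfonate, 71 were higher in ΔCclaeA, 56 in Δrpn-4 and 142 in Δtah-1, against 45.6, 39.3 and 103 for independent lists, and after scaling 106, 203 and 241, against 72.9, 164 and 210. Of the same 1355 IDs, 101 were lower in ΔCclaeA, 305 in Δrpn-4 and 286 in Δtah-1, against 125, 473 and 253. After scaling, 74, 22 and 190 were lower, against 119, 53.7 and 147. The WT lignosulfonate libraries enter both sides of this comparison with opposite signs. The covariance of fold changes differed from that of simulated unchanged groups by -0.247 for ΔCclaeA, -0.115 for Δrpn-4 and 0.053 for Δtah-1.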

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

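Counts of IDs called in opposite directions in a pair of mutants were chosen after the calls were seen. All of these IDs were also called in the direct contrast between the 2 mutants, with either scaling, but opposite 2-fold calls against the same WT libraries leave that contrast almost no room to fail, so it adds little. Each count is given beside that of independent lists. Of the IDs lower in ΔCclaeA, 88 were higher in Δrpn-4, against 24.7, and 152 were higher in Δtah-1, against 64.9. Of the IDs higher in ΔCclaeA, 107 were lower in Δtah-1, against 58.2, and 88 IDs were higher in Δrpn-4 and lower in Δtah-1, against 50.2. The remaining counts lay below those of independent lists: 78 IDs were higher in ΔCclaeA and lower in Δrpn-4, against 109, and 139 were lower in Δrpn-4 and higher in Δtah-1, against 246. In the same order, median-of-ratios scaling gave 148, 170, 83, 122, 12 and 40 IDs, against 64.2, 82.3, 35.4, 79.7, 12.9 and 37.3, so that the last counts were close to those of independent lists. With both scalings 78, 126, 59, 66, 11 and 29 IDs were found.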

How the results depend on the processing

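Chosen after seeing the data were the removal of the 100 most abundant genes, the overlaps in opposite directions between mutants, and, for contrasts between mutants, overlaps and the lignosulfonate response in the mutants, the settings with no minimum fold change, TPM, the 6 compared libraries or 1 replicate left out. All 173 values of the named IDs, each in the comparison that named it, kept their direction and call, but not their size, under the alternatives run for them. TPM, no minimum fold change and removal of the 100 most abundant genes were not run for named IDs, and yc1106_06671 had no value without a glucose library, where it did not pass the filter. With a pseudocount of 0.1 the log2 fold changes were -15.49 for yc1106_06671, -13.23 for yc1106_04105, 13.14 for yc1106_06939, -10.49 for yc1106_04001, -9.61 for yc1106_06359 and 7.48 for yc1106_01883. Gene list tests were not run under any setting. A pseudocount of 0.1, no filter and the 6 compared libraries kept every count of changed IDs within 1.5 times of that reported. The depth in reads is unknown, which leaves the precision of low FPKM values unknown.

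With median-of-ratios scaling, 1203 IDs changed in Δrpn-4 against WT and 2053 between ΔCclaeA and Δrpn-4. Overlaps for ΔCclaeA and Δrpn-4 then held 61 IDs higher in both, 12 higher in ΔCclaeA and lower in Δrpn-4, 148 lower and higher, and 79 lower in both. For ΔCclaeA and Δtah-1, 68 were higher in both and 159 lower in both. For Δrpn-4 and Δtah-1, 238 were higher in both, 40 lower in Δrpn-4 and higher in Δtah-1, and 58 lower in both. Of IDs higher on lignosulfonate, 147 were lower in Δrpn-4 and 207 in Δtah-1, and of IDs lower on it 203 and 241 were higher. This scaling sets the median change near 0, which in the mutants by construction moves IDs from the lower to the higher side.

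With no minimum fold change, which by construction adds calls, 6428 IDs changed on lignosulfonate, 3416 in ΔCclaeA, 7082 in Δrpn-4 and 5504 in Δtah-1 against WT. Between mutants the counts were 6580 for ΔCclaeA and Δrpn-4, 5867 for ΔCclaeA and Δtah-1 and 6023 for Δrpn-4 and Δtah-1. In the order higher in both, higher then lower, lower then higher and lower in both, overlaps were 110, 977, 231 and 1330 for ΔCclaeA and Δrpn-4, 163, 969, 439 and 866 for ΔCclaeA and Δtah-1, and 172, 272, 691 and 3232 for Δrpn-4 and Δtah-1. Of IDs higher on lignosulfonate, 1136, 2640 and 1459 were lower in ΔCclaeA, Δrpn-4 and Δtah-1, and of IDs lower on it 570, 201 and 381 were higher.

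With TPM, 146 IDs were higher in ΔCclaeA and lower in Δrpn-4, 60 higher in ΔCclaeA and Δtah-1, and 263 lower in Δrpn-4 and higher in Δtah-1. TPM also gave 1098 IDs lower in Δtah-1 than in WT, and 451 higher and 3780 lower in Δrpn-4 than in Δtah-1. The cause was not tested. Without the 100 most abundant genes, 2033 IDs changed in Δrpn-4, 1654 of them lower, 1895 were higher in ΔCclaeA than in Δrpn-4, 45 were higher in ΔCclaeA and lower in Δrpn-4, 210 lower in both, and 361 lower in Δrpn-4 and Δtah-1.

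Deviations of same-numbered libraries from group means correlated at -0.215 to 0.508, and in no comparison all over 0.1. The WT media gave 0.01, 0.441 and 0.508, so pairing is open there. With the replicate block, 3765, 1171, 3504 and 2439 IDs changed on lignosulfonate, in ΔCclaeA, in Δrpn-4 and in Δtah-1, and no count moved by over 1.5 times.

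Leaving out 1 replicate gave 3593 to 3899, 1091 to 1198, 3268 to 3825 and 2364 to 2820 changed IDs in the same order, the last value without Δtah-1 replicate 2. The lowest share of calls kept in direction in these comparisons was 88.5%. Between Δrpn-4 and Δtah-1 the lowest share kept was 77.2%.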

Other observations

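The tests chosen only after the result was seen are the check for a mislabelled Δtah-1 library, the tests of overall scale and of depth, for which related values had been seen, the tests for Δtah-1 replicate 2 on 7 genes and on genes far from WT, and the lowest ratio in each mutant. Runs of IDs were also picked after the values were seen.

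A further run shared by mutants was yc1106_04667 to yc1106_04672, the longest run in ΔCclaeA called with both scalings. Its 6 IDs were lower in ΔCclaeA, with a median of the group means of 43.4 FPKM against 296 in WT on lignosulfonate and 74.3 on glucose. In Δrpn-4, 5 of the 6 were lower with both scalings, with a median of 76.3 FPKM. In Δtah-1, 3 were lower as deposited and 2 after scaling, with a median of 117 FPKM. Runs of at least 5 IDs called with both scalings numbered 23 for lignosulfonate against glucose, 3 for ΔCclaeA, 1 for Δrpn-4 and 4 for Δtah-1.

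Neighbouring IDs were called in the same direction more often than random placement gives. In ΔCclaeA there were 202 such pairs against a mean of 83.6 in 100000 random placements, a ratio of 2.42, and 2.69 with median of ratios (one-sided permutation p = 1e-05, the smallest the placements can give). In the other comparisons the ratio was 1.53 for lignosulfonate, 1.29 for Δrpn-4 and 1.66 for Δtah-1, and 1.57, 2.56 and 2.07 with median of ratios. Reads shared evenly between near-identical neighbours would give similar levels. The median absolute log2 ratio within the 202 pairs was 1.74, against 2.15 between called IDs drawn at random. This argues against even sharing for the pairs as a set. However, 27.7% of the pairs lay within 2-fold, so shared reads stay open for part of them, and uneven sharing was not tested. Whether neighbouring IDs are regulated together stays open, since the ratio of 2.42 restates the pattern, and genome positions and split or overlapping gene models were not tested.

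Most FPKM values were lower in Δrpn-4 than in WT on lignosulfonate, with a median log2 difference per library of -0.77 to -0.79. Without the 100 genes of highest mean FPKM over all 15 libraries, and with the rest rescaled to equal sums, the 3 medians lay between -0.50 and -0.52 (highest -0.50). This argues against those 100 genes as the whole cause. They were not ranked by level in Δrpn-4, whose own 100 most abundant IDs held 51.0% of its FPKM sum. Before rescaling the mean sums were 1018220 in Δrpn-4 and 914412 in WT on lignosulfonate. The medians before and after removal are therefore not on the same scale, and the part due to those genes was not measured. Lower depth is argued against by relative depths of at least 1.01 in the 3 libraries. A shift spread over abundant transcripts outside those 100, the authors' normalization and an effect of the genotype itself stay open, and no test separated them.

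Replicate 2 of Δtah-1 stood apart from replicates 1 and 3, and no biological explanation was tested. A scale factor shifts all log2 values alike and leaves the SD of log2 differences almost as it is, and that SD was at least 1.41 times that between replicates 1 and 3, which argues against overall scale as the whole cause. A mislabelled library of another group is argued against by its correlation across genes of 0.964 with replicates 1 and 3, above the highest with another group, 0.864. Admixed WT RNA would bring all abundant WT transcripts, but the planned selection, only 2 genes of at least 50 FPKM in WT and under 1 FPKM in replicates 1 and 3, had a median of 0 of the WT level in replicate 2, and 7 genes of a wider selection reached at most 0.022, which argues against a share much above that. Over 363 genes at least 4-fold from WT in replicates 1 and 3, replicate 2 lay nearer to WT by a median of 0.15 (log2), but replicates 1 and 3 left out in the same way shifted by 0.17 and 0.07, so this test decides nothing and a difference between cultures stays open.

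One hypothesis was that the deleted gene of each mutant is among IDs near 0 in that mutant only, under 1 FPKM in all 3 of its libraries and at least 5 FPKM in the other 9 lignosulfonate libraries. Such IDs numbered 8 in ΔCclaeA, 2 in Δtah-1 and 0 in Δrpn-4, so that 2 of the 3 mutants had any, which goes against the hypothesis as stated for all mutants. They included the named yc1106_04001 in ΔCclaeA, and were yc1106_06359 and yc1106_01886 in Δtah-1. Whether such a fall is a response or the deletion itself was not tested. In Δrpn-4 the lowest ratio of its highest library to the lowest of the other 9 was 0.183, for yc1106_08298. A deleted gene with low expression in WT, with reads left from an undeleted part or without an ID would not be found this way, and none of the IDs is taken here as a deleted gene.

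For each count of changed IDs the 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave the largest count. Every other split puts libraries of both groups on each side, so a real difference widens the spread within a side. Few calls in those splits follow from that, and their counts do not measure what unchanged libraries would give. The real and the highest other count were 3760 and 1 for lignosulfonate against glucose, 1164 and 0 for ΔCclaeA, 3503 and 0 for Δrpn-4, and 2434 and 1 for Δtah-1, each against WT. Between mutants they were 3506 and 1 for ΔCclaeA and Δrpn-4, 3227 and 1 for ΔCclaeA and Δtah-1, and 2903 and 0 for Δrpn-4 and Δtah-1.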
